A study of Mus musculus with 2 samples.

How the data were processed

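Total RNA from the thymus of 2 newborn pups was measured by what the labels call single cell RNA-seq, with a linked protocol document named for Smart-seq, from 13 pg of RNA with spike-ins. RNA was extracted with the mirVana kit and restricted to more than 200 nt, per the labels. The labels give both libraries as biological replicates of 1 tissue, from pups 6 and 7 of a Charles River female, and list the same donor for both, so the spread between replicates holds pup, RNA handling and library together. Groups and replicate numbers were taken from the labels, and all samples were used.

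The deposited tables hold, for each gene and transcript, a length, an effective length, an expected count (an estimated count of reads that need not be whole) and TPM, with posterior mean versions of both. Per the labels the assembly was mm10, and the deposited text notes name annotation M4. The aligner and the program that estimated the counts are not given in the sources used here. Per the file headers the columns carry the names that the RSEM program writes. In the deposited tables the TPM values sum to 1000000 in each library over genes and spike-ins together, the effective length is 99 bases below the length, and each library has its own table with nothing pooled. A gene's TPM depends on which transcripts the authors' estimate chose, and for features barely longer than 99 bases a few counts give a large TPM. Reads shared by near-identical genes were divided by the authors' estimate.

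Mouse gene IDs (43346) were matched to GENCODE M21 on GRCm38, the assembly also called mm10, by ID without version. There 42462 were found and 884 were not, and the latter held 0.197% and 0.133% of mouse counts. Names, types and positions come from M21. Another 26248 entries with numeric IDs and 96 ERCC spike-ins were kept apart. TPM was rescaled to 1000000 over mouse genes in each library, and ratios are log2 of replicate 2 over replicate 1 with a pseudocount of 1 TPM. Folds stated as "at least" compare counts per mouse count with a floor of 3 counts per library, the most that a count of 0 allows at 95%. Ratios against 1 to 3 counts carry an exact counting interval. Reads were not marked with molecular identifiers in the tables, so intervals and floors cover counting error only. They set no lower limit on a difference in expression. The floor of 3 counts equals 0.115 and 0.0940 counts in each 1000000 mouse counts of replicates 1 and 2.

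Before the data were examined, 30 gene lists, the measures, the alternatives and the rule for named genes were fixed. Of the lists, 26 name genes (T lineage, double-positive, early progenitor, mature single-positive, gamma-delta, thymic epithelium, mesenchyme, endothelium, erythroid, macrophage and dendritic, MHC class II, B cell, neutrophil and mast, parathyroid and thyroid, fat, heart and skeletal muscle, nerve, other organs, G2 and M phase, S phase, recombination and repair, apoptosis and selection, immediate-early and stress, housekeeping, sex-linked, nuclear noncoding), and the remaining 4 are name patterns (mitochondrial, ribosomal protein, replication histone, V, D and J segments). Names without a match in M21 stayed out, 4 of the 15 gamma-delta names, 3 of the 16 erythroid names and 3 of the 10 nuclear noncoding names. Named genes were the 20 of highest mean TPM outside spike-ins and mitochondrial genes, up to 5 members of each list by mean TPM, list members at 10 or more counts in 1 library and 0 in the other, the 10 of largest log2 ratio in each direction among genes with a mean of 100 or more counts, all sex-linked members, and the dominant transcripts of up to 6 T-lineage genes. Mitochondrial genes and any gene said to be named after its values were seen fall outside that rule. Not every gene that the rule selected is named in the text.

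Levels are given as mean ± SD of 2. No test between groups was possible with 1 group, and no p-value is given for a difference between the libraries. In the closing section, Fisher's exact test compares how many genes of given lists were read. Its p-value counts genes as independent units, which they are not, and describes these libraries only. The scatter of the log2 ratio was measured as the median absolute deviation, scaled to equal the SD of a normal distribution, in bins of mean expected count, beside the value from 20 simulations of Poisson read counting. A list's median log2 ratio, over members with a mean of 10 or more counts, was placed among 10000 random lists of the same size, drawn within 100 ranks of each member's mean TPM, for lists with 5 or more such members. The alternatives were posterior mean estimates, TPM with spike-ins kept or without mitochondrial genes, other pseudocounts, count minimums, detection levels and fold thresholds, counts scaled with edgeR TMM factors or DESeq2 size factors, thinning of the deeper library, plain SDs, other rules for the dominant transcript and each library alone. For edgeR, DESeq2 and thinning, expected counts were rounded to whole numbers. Leaving out genes with an effective length under 100 bases was added after seeing the data.

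The measures were tested on simulated data. With Poisson read counting only, 199 of 200 genes changed 8-fold and 0 of 200 genes changed 2-fold passed the 4-fold threshold among 9341 genes, and 0 unchanged genes did. Of 200 random lists, 2.5% lay outside the central 95%, and 100 of 100 lists of 20 abundant genes shifted 4-fold were found. The number of molecules per TPM, used in the closing section, was recovered at a median of 0.0200 from 20 simulations with a true value of 0.02 (0.0164 to 0.0305). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 were used.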

Results

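RNA longer than 200 nt from the thymus of newborn mice (postnatal day 0, strain B6NCrl) was sequenced in 2 libraries, each made from 13 pg of total RNA, the amount that the labels equate with 1 cell. The thymus is the organ in which T cells mature, and its RNA came from whole tissue, so each library drew on the transcripts of many cell types. Replicate 1 came from pup 6 and replicate 2 from pup 7, for which the labels list 1 donor. Both libraries belong to 1 group, so the data give expression levels and the agreement between 2 pups, with no other condition to compare. The tables held 27003123 expected counts in replicate 1 and 32980032 in replicate 2, of which 25999043 and 31902773 fell in mouse genes. At 1 or more counts, 10275 genes were read in replicate 1 and 11764 in replicate 2 (mean 11019.5 ± 1053, SD, n = 2). Protein-coding genes held 93.6% ± 0.0381 of mouse counts, mitochondrial genes 2.34% ± 0.0262, ribosomal protein genes 4.22% ± 0.575 and replication histone genes 0.237% ± 0.0913. The mitochondrial share leaves out nuclear copies of mitochondrial sequence. The 10 most abundant genes took 5.29% ± 0.0748 of mouse counts and the top 100 took 18.2% ± 1.10. Spike-in RNA of the External RNA Controls Consortium (ERCC) took 3.72% of counts in replicate 1 (95% exact binomial interval 3.71 to 3.73) and 3.27% in replicate 2 (3.26 to 3.27), which left 25.9 and 29.6 mouse counts per spike-in count.

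T-lineage transcripts were the most abundant of the cell type lists. The 28 T-lineage genes summed to 20253 ± 600 TPM (SD, n = 2), a unit that corrects counts for transcript length and depth, and 27 of them were at 1 or more counts in both libraries. Trbc2 and Trbc1, the constant genes of the T-cell receptor beta chain, stood at 6268 ± 327 and 3358 ± 293 TPM. They are near-identical copies, so the split between them is uncertain. Lck, the kinase that acts first in T-cell receptor signalling (chromosome 4, 129548344 to 129573641, minus strand), stood at 1413 ± 14.2 TPM, Coro1a at 1253 ± 26.7 TPM and Cd3g at 917 ± 286 TPM. Cd5, a surface receptor that tunes T-cell receptor signals, had 0 counts in replicate 1 and 4071 in replicate 2. In read counts that is at least 1106-fold against the floor of 3 counts per library. Such a bound covers read counting only and sets no lower limit on a difference in expression.

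Genes of double-positive thymocytes, the stage that carries both CD4 and CD8, summed to 3015 ± 716 TPM, with 17 of 20 read in both libraries. Cd8b1 (chromosome 6, 71322788 to 71337494, plus strand) stood at 908 ± 119 TPM, Cd8a at 266 ± 48.6, Aqp11 at 267 ± 80.6 and Themis at 217 ± 39.4. Cd4, named after its values were seen, stood at 159 ± 68.9 TPM. The antigen-presenting gene Cd1d1 had 0 and 2009 counts. Ikzf3 had 39 and 0 counts. The 14 genes of V(D)J recombination and DNA repair, 3 of which are also on the double-positive list, summed to 3431 ± 2.71 TPM. Hmgb1 gave most of that sum, at 2118 ± 356 TPM, followed by Hmgb2 at 442 ± 45.4, Xrcc6 at 409 ± 177 and Rag1, a subunit of the recombinase (chromosome 2, 101638282 to 101649501, minus strand), at 169 ± 72.6. Lig4 stood at 17.1 and 108 TPM. The 5 members Nhej1, Poll, Xrcc4, Prkdc and Dclre1c were read in replicate 2 alone, with 0 counts in replicate 1.

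Genes of other thymocyte stages were lower. Early progenitor genes summed to 221 ± 4.25 TPM, with 7 of 16 read in both libraries, 6 in 1 library and 3 in neither. Notch1, the receptor that commits progenitors to the T lineage, stood at 90.7 ± 7.12 TPM and Il2ra at 45.2 ± 11.2 TPM, while Kit had 0 and 2415 counts and Spi1 had 872 and 0. The mature single-positive list summed to 1054 ± 355 TPM, led by the chemokine receptor Ccr9 at 336 ± 187 TPM. Whether its members are restricted to that stage was not tested, so the sum does not measure mature cells. Of its 16 genes, 9 were read in both libraries and 4 were below 10 counts in both. Those 4, named after their values were seen, were Klf2, Foxp3, Cd40lg and Il2rb. The gamma-delta list summed to 1297 ± 77.1 TPM, of which Cd3g, also on the T-lineage list, gave 917 TPM. Its receptor constant genes Tcrg-C2 and Tcrg-C1 stood at 199 ± 169 and 131 ± 23.4 TPM, and Tcrg-C4 had 0 and 650 counts. Among 229 named V, D and J segments of the T-cell receptor loci, 25 were read in both libraries, 41 in 1 library and 163 in neither. The effective length, 99 bases below the length, leaves nothing to segments of 99 bases or fewer. The 163 therefore do not show absent expression, and how many were that short was not counted. Their sum was 5889 ± 854 TPM, and Trbv16 was the highest at 521 ± 75.0 TPM.

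Thymic epithelium, the stroma that instructs and selects thymocytes, summed to 3948 ± 101 TPM over 20 genes, of which 15 were read in both libraries. The keratins Krt18 and Krt8 stood at 890 ± 219 and 809 ± 52.7 TPM. The chemokine Ccl25, which draws progenitors into the thymus (chromosome 8, 4325210 to 4360020, plus strand), stood at 757 ± 141, Ccl21a at 383 ± 36.1 and Tbata at 365 ± 57.0 TPM. Foxn1, the master regulator of thymic epithelium (chromosome 11, 78357577 to 78386558, minus strand), had 0 and 1129 counts, and the Notch ligand Dll4 had 2471 and 0. Enpep had 0 and 2260 counts and Fezf2 had 0 and 696. Aire, the factor that drives tissue antigens in the medulla and a gene named after its values were seen, had 28 and 1158 counts. MHC class II genes summed to 5168 ± 1034 TPM, with H2-Ab1 at 1806 ± 923, Cd74 at 1586 ± 114 and H2-Aa at 1157 ± 385 TPM, and H2-DMa had 0 and 1765 counts.

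Other cell types of the organ were present at lower sums. Mesenchyme genes summed to 1876 TPM in replicate 1 and 1877 in replicate 2, led by Sparc at 766 ± 273 and the collagen Col3a1 at 302 ± 95.9 TPM, and 14 of 16 were read in both. Macrophage and dendritic genes summed to 1006 ± 324 TPM, with Tyrobp at 219 ± 191 and the complement gene C1qb at 207 ± 43.9 TPM. Endothelial genes summed to 337 ± 115 TPM, led by Egfl7 at 104 ± 72.1, and Cldn5 had 1888 and 0 counts. B-cell genes summed to 435 ± 152 TPM, most of it from the immunoglobulin gene Ighm at 404 ± 110 TPM. Neutrophil and mast cell genes summed to 79.1 and 37.3 TPM, with no member at 10 or more counts in both libraries. Fat genes summed to 528 and 217 TPM, mostly Fabp4 at 323 ± 151 TPM. Nerve genes summed to 72.0 TPM in replicate 1 and 0.0961 in replicate 2, where the neuronal tubulin Tubb3 had 2459 and 3 counts, a ratio of 1006 after scaling to library size (95% counting interval 344 to 4881). Parathyroid and thyroid genes summed to 90.4 and 60.4 TPM, in which Pth, the parathyroid hormone gene, had 799 and 0 counts and Tg, the thyroglobulin gene, had 0 and 1605.

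**Figure D1:**
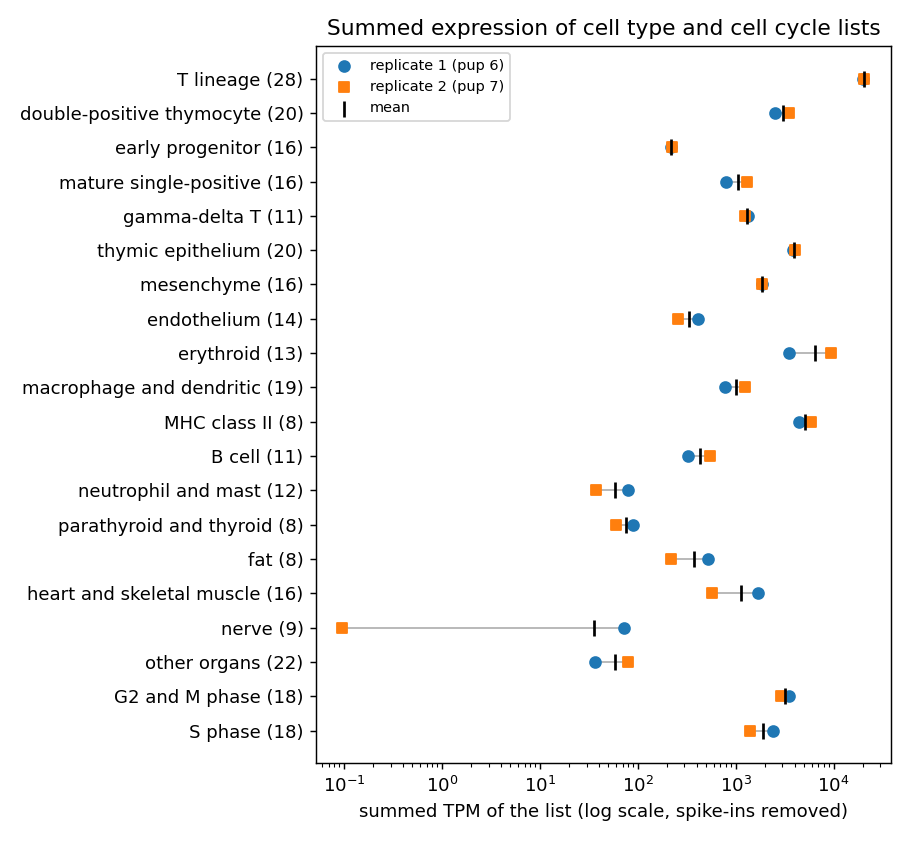
Summed TPM of 20 lists in the 2 libraries, on a log axis, with circles for replicate 1, squares for replicate 2, black ticks for their mean and the number of measured genes in brackets. The T-lineage sums lie close together (19829 and 20678 TPM), while the erythroid sums lie apart (3547 and 9490 TPM) and the nerve sums farthest apart (72.0 and 0.0961 TPM).

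Erythroid transcripts summed higher in replicate 2 and muscle transcripts in replicate 1. The erythroid list summed to 3547 TPM in replicate 1 and 9490 in replicate 2. Its 7 members with a mean of 10 or more counts were all higher in replicate 2. The adult globins led it, with Hba-a2 at 1776 and 4477 TPM (chromosome 11, 32296489 to 32297298, plus strand), Hbb-bs at 859 and 2273, Hba-a1 at 697 and 1512 and Hbb-bt at 150 and 818. Hba-a1 and Hba-a2 are near-identical copies, as are Hbb-bs and Hbb-bt, so the split within each pair is uncertain. Bpgm, which makes the red cell metabolite that lowers oxygen affinity, had 9 and 11328 counts. Heart and skeletal muscle genes summed to 1676 TPM in replicate 1 and 581 in replicate 2, and 15 of the 16 were read in both. Actc1, the cardiac actin, stood at 513 and 95.2 TPM, the atrial myosin light chain Myl7 at 192 and 147, Tnni3 at 138 and 55.4 and Myl1 at 118 and 74.8, while Nppa, the atrial natriuretic peptide gene, had 4312 and 0 counts. The 22 genes that mark other organs summed to 36.3 and 79.7 TPM, and 20 of them were below 10 counts in both libraries. The exceptions were Mbp at 48.8 ± 43.7 TPM and Afp with 739 and 0 counts.

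Cell cycle transcripts were abundant. G2 and M phase genes summed to 3205 ± 440 TPM, with 17 of 18 read in both libraries and Birc5, Ccnb1 and Ccnb2 at 453 ± 55.2, 436 ± 155 and 418 ± 56.3 TPM. S phase genes summed to 1889 ± 706 TPM, led by Pcna, the sliding clamp of DNA replication, at 349 ± 44.2 TPM, and Rrm2 stood at 357 and 101 TPM. Replication histone genes summed to 7211 ± 2397 TPM, of which Hist1h2ap gave 5182 ± 1799. Many histone genes are near-identical, so values of single members are uncertain. Apoptosis and selection genes summed to 931 ± 160 TPM, led by Trp53 at 220 ± 82.1, and Bax had 0 and 1607 counts. Immediate-early and stress genes summed to 2226 ± 249 TPM, mostly the chaperone Hspa8 at 959 ± 12.2 and Hsp90aa1 at 515 ± 168, and Ier2 had 0 and 4476 counts. Nuclear noncoding genes summed to 6518 ± 426 TPM, of which Malat1 gave 6141 ± 569.

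Genes that every cell uses were frequent among the 20 most abundant outside the mitochondrial genome. Actb stood at 5846 ± 567 TPM, Eef1a1 at 5020 ± 641, Ubb at 5016 ± 141, Ppia at 4976 ± 1034, Ftl1 at 4557 ± 573, Tmsb4x at 4238 ± 770, Rpl41 at 3954 ± 210, Rps19 at 3179 ± 63.4 and H3f3b at 3118 ± 611. The ribosomal protein name pattern, which also takes in pseudogenes and kinases of the S6 family, summed to 100180 ± 7135 TPM over 344 genes, and the 16 housekeeping genes summed to 24423 ± 2221 TPM. The 37 mitochondrial genes summed to 41156 ± 2003 TPM, with mt-Atp6, named after its values were seen, highest at 11450 ± 156. Several of the top 20 are uncertain. Gm28437 (10891 ± 2824 TPM), Gm29216 (5536 ± 1855) and Gm28661 (3251 ± 581) are nuclear copies of mitochondrial sequence. They are outside the mitochondrial sum and share, which may therefore be too low. Gm10123 is a processed pseudogene close to Ppia, and Gm42418 (5192 ± 703 TPM) is annotated as a long noncoding RNA. Gm22133 lies inside Ftl1 with an effective length of 10 bases, which turned 1042 and 977 counts into 4664 ± 614 TPM.

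Abundant genes were read in both pups, while many genes of lower level were read in 1 alone. Every mouse gene with a mean of 500 TPM or more was read in both libraries, whereas 13.5% of the 1650 genes between 50 and 100 TPM and 37.0% of the 2078 genes between 25 and 50 TPM had 3 or fewer counts in 1 library. Of the 10624 genes at 1 TPM or more in either library, 5809 reached that level in both (54.7%, 95% exact binomial interval 53.7 to 55.6). Across all 43346 mouse genes Pearson's r of log2(TPM + 1) was 0.741 and Spearman's rho was 0.710. Genes are not independent replicates, and many of them were at 0 in both libraries. Among the 9341 genes with a mean of 100 or more counts r was 0.263 and rho 0.381, and among genes with a mean of 1 TPM or more they were 0.303 and 0.371. The robust SD of the log2 ratio was 5.28 at mean counts of 100 to 1000, 3.06 at 1000 to 3000, 1.31 at 3000 to 10000, 0.68 at 10000 to 30000 and 0.38 from 30000. At 100 to 1000 and 1000 to 3000 counts, 64.5% and 29.5% of genes had 3 or fewer counts in 1 library. The spread there thus also holds genes missing from 1 library. Scaled count ratios gave 12.003 at 100 to 1000, and the plain SD was 2.10 at 3000 to 10000. Poisson counting of the reads alone gave 0.05 at 1000 to 3000 and 0.01 from 30000. Spike-ins also parted, with 30 of 96 read in both libraries and 10 in 1 library, but those in the highest bins scattered less than mouse genes, at 0.29 and 0.12. At lower TPM their shares at 3 or fewer counts in 1 library were above those of mouse genes. These were 2 of 7 spike-ins at 50 to 100 TPM and 5 of 6 at 25 to 50 TPM.

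**Figure D2:**
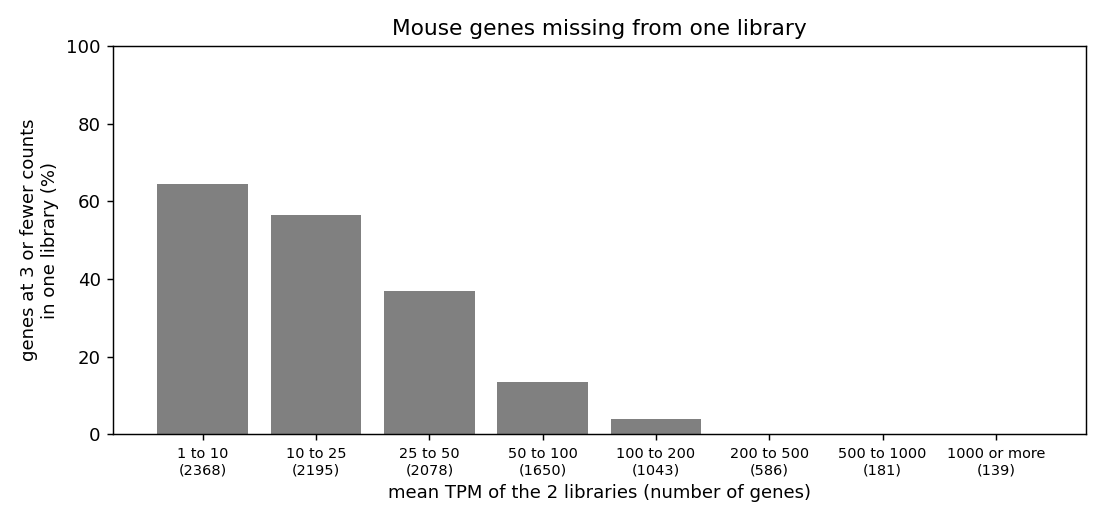
Percentage of mouse genes at 3 or fewer counts in 1 of the 2 libraries, in ranges of mean TPM, with the number of genes in brackets. The share falls from 64.6% at 1 to 10 TPM to 3.93% at 100 to 200 TPM and is 0 from 500 TPM.

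Among the 9341 genes with a mean of 100 or more counts, 4751 differed at least 4-fold between the pups (50.9%), 2747 of them higher in replicate 2 and 2004 higher in replicate 1. Without a minimum count the number was 5179 of all 43346 mouse genes (11.9%). With 1 library from each pup this difference has no replicate check, and no p-value is given. The folds and intervals below cover read counting only and set no lower limit on a difference in expression. Of the 9341, 1991 had 3 or fewer counts in replicate 1 and 1286 in replicate 2. The 10 genes of largest log2 ratio in each direction had 9 or fewer counts in the lower library. Higher in replicate 2 were Rae1, an RNA export factor (0 and 13269 counts, at least 3605-fold), Cdca2 (0 and 14021, at least 3809-fold), the V segment Trgv2 (0 and 1768, at least 480-fold), the glutathione synthase gene Gss (0 and 8684, at least 2359-fold), Blvrb (0 and 4576, at least 1243-fold) and Prkrip1 (0 and 2999, at least 815-fold). Usp22 had 1 and 6592 counts, a ratio of 5372 (95% counting interval 964 to 212219), Gm26870 had 1 and 6250, a ratio of 5094 (914 to 201211), and Bpgm is given with the erythroid genes. Gm10800, a repeat-rich gene model whose reads are uncertain, had 0 and 7553. Higher in replicate 1 were Nppa (at least 1764-fold), Sgf29 (3474 and 0 counts, at least 1421-fold), Mea1 (4235 and 0, at least 1732-fold), Syce2 (5219 and 0, at least 2135-fold), Mindy1 (8566 and 0, at least 3504-fold) and Snhg6 (2867 and 0, at least 1173-fold). Osgep, Telo2 and Naa60 had 7378, 8722 and 7922 counts in replicate 1 and 1 count each in replicate 2, ratios of 9053 (1624 to 357636), 10702 (1920 to 422776) and 9721 (1744 to 384002). Coa7 had 3292 and 2 counts, a ratio of 2020 (559 to 16685).

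**Figure D3:**
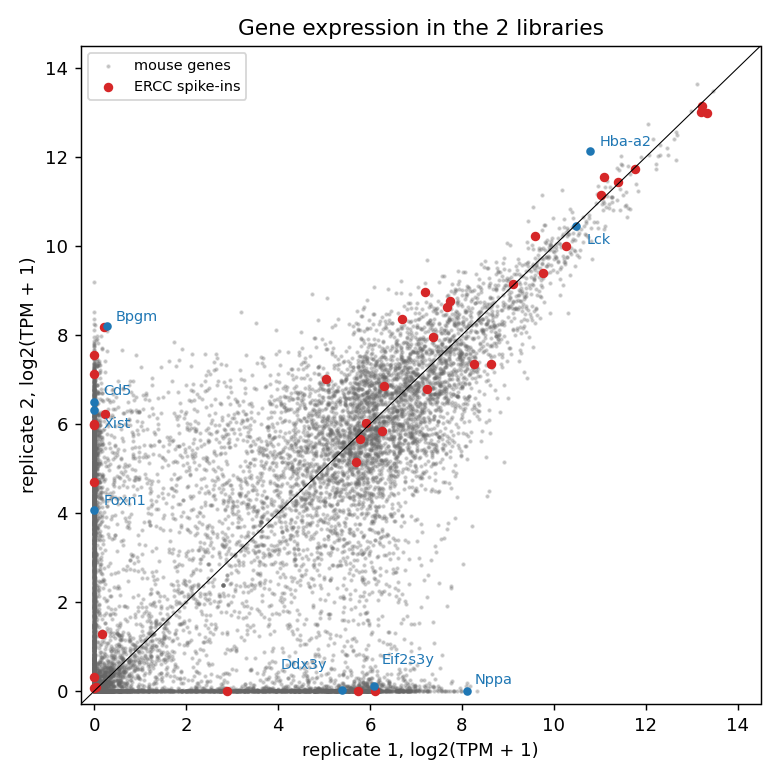
Expression of mouse genes with at least 1 count in either library (grey) and of ERCC spike-ins (red) in replicate 1 and replicate 2, as log2(TPM + 1), with genes picked by hand in blue and the line of equality in black. Genes of high TPM such as Lck lie near the line, while Cd5, Foxn1, Bpgm and Xist lie on or near the axis of replicate 2 and Nppa, Ddx3y and Eif2s3y on that of replicate 1.

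All 7 erythroid genes measured were higher in replicate 2, by unlike amounts. Their log2 ratios ran from 0.18 for Alas2, named after its values were seen, to 7.94 for Bpgm. The globins among them are near-identical pairs with shared reads, which the random lists do not mirror. The erythroid median log2 ratio of replicate 2 over replicate 1 was 1.40, at the 99.95th percentile of 10000 random lists of the same size and similar expression. The gamma-delta list lay at 1.99 (percentile 99.05), with 5 of 7 members higher in replicate 2, although its sum was higher in replicate 1 (1352 and 1243 TPM). The recombination and repair list lay at 0.90 (percentile 98.3), or 1.22 with the 5 members at 0 counts set to their bound, while its sums were 3429 and 3433 TPM. V, D and J segments lay at -0.56 (percentile 1.35), with 34 of 59 higher in replicate 1, and replication histones at -0.73 (percentile 2.48), with 23 of 37 higher in replicate 1. The other 18 of the 23 lists with 5 or more measured members lay inside the central 95% of their random lists. These included T-lineage genes (0.09), double-positive genes (0.27), epithelium (0.51), G2 and M phase (-0.27), S phase (-0.67, percentile 4.64), muscle (-0.72) and ribosomal proteins (-0.11). MHC class II genes had a median of -0.15 although their sum was higher in replicate 2, and nuclear noncoding genes a median of 0.81 although theirs was higher in replicate 1 (6820 and 6217 TPM). Of 200 random lists tested, 2.5% lay outside their central 95%. Percentiles describe these 2 libraries only. When a mean of 100 or more counts was required, 1 list stayed outside, the erythroid one, and the V segment median moved to -0.24 (percentile 19.7).

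The most abundant transcript of a gene was often not the same in both pups. Compared were 4870 genes with several transcripts, a mean of 100 or more counts and some TPM in both libraries. Genes without TPM in 1 library were left out. The minimum was on the mean count, so the call in 1 library could rest on few reads. Of the 4870, 2822 had the same dominant transcript (57.9%, 95% exact binomial interval 56.5 to 59.3). The share rose with depth from 45.1% at mean counts of 100 to 1000 to 91.1% from 30000. Of the 6 most abundant T-lineage genes compared, 5 had the same dominant transcript in both libraries. Tcf7-201 gave 99.94% and 99.98% of Tcf7, Coro1a-201 gave 92.2% and 97.4% of Coro1a, Cd3g-201 gave 92.3% and 95.2% of Cd3g, Trbc1-202 gave 91.5% and 86.6% of Trbc1, and Lck-201 gave 47.0% and 50.4% of Lck. Skap1, an adaptor of T-cell adhesion, was led by Skap1-206 in replicate 1 (34.9%) and by Skap1-201 in replicate 2 (39.1%).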

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

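The tables list 26248 short entries under numeric IDs, outside the mouse genes and spike-ins that the report compares. They held 12.96 expected counts in replicate 1, above the 3 counts that a count of 0 allows, and 0 in replicate 2. No explanation of this was tested.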

How the results depend on the processing

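The alternative that left out genes with an effective length under 100 bases was chosen after seeing the data. No list outside its central 95% changed direction, and no named gene with a log2 ratio of 2 or more in either direction did. Direction was not checked for other results. Of 30 list levels, those that moved by 1 SD or more numbered 7 with spike-ins kept in the total, 5 without mitochondrial genes, 2 with posterior means and 2 without the short genes. Keeping spike-ins scaled every list by 0.935 to 0.936, dropping mitochondrial genes by 1.041 to 1.044 and dropping short genes by 1.009 to 1.011. In these settings, which lists moved depended on how small the SD of their 2 sums was, and shows no differing sensitivity. With spike-ins kept in the total, which lowers every level, the sums were 18947 TPM for the T lineage, 207 for early progenitors, 1214 for gamma-delta, 3694 for epithelium, 1755 for mesenchyme, 3210 for recombination and repair and 38503 for mitochondrial genes. Without mitochondrial genes in the total, which raises every level, they were 21123 for the T lineage, 231 for early progenitors, 4118 for epithelium, 1957 for mesenchyme and 3578 for recombination and repair. Mesenchyme and recombination stood at 1837 and 3348 TPM with posterior means and at 1895 and 3465 without the short genes. The share of genes detected in both libraries was 66.3% with posterior means, 57.1% above 0.1 TPM, 52.5% from 5 TPM, 59.8% from 1 count and 59.6% after thinning. With posterior means 14090 genes reached 1 TPM in either library, in place of 10624, so the sets differ. Pearson's r was 0.759 with posterior means, 0.728 with a pseudocount of 0.1, 0.727 on scaled counts, 0.303 over genes at 1 TPM or more and 0.263 over genes at 100 counts or more, and Spearman's rho was 0.850 with posterior means and 0.371 and 0.381 over those genes. Dropping genes at 0 in both libraries lowers both by construction. At mean counts of 10 to 100 the scatter was 1.42 with posterior means, 1.90 as a plain SD and 7.24 from count ratios, and at 100 to 1000 it was 4.96, 3.98 and 12.003. The plain SD was 3.66, 2.10 and 0.84 in the next 3 ranges. With a minimum mean count of 100, 1 of 23 lists lay outside the central 95%, and the medians were 1.99 for gamma-delta (percentile 96.6), 0.91 for recombination (92.6), -0.60 for histones (5.19) and -0.24 for V, D and J segments. With posterior means they were 0.90 for recombination (97.49), -0.73 for histones (2.92) and 0.19 for mitochondrial genes, now outside (97.8), and without mitochondrial genes in the total -0.73 for histones (2.70). The same transcript dominated in 61.4% of genes from 1000 counts, 44.1% with posterior means and 63.8% where it held 50% or more in both. Posterior means gave more genes a value above 0 in both libraries, so 6600 genes were compared in place of 4870. Where no construction is named, the cause was not tested. The 11 alternative counts of genes past the fold threshold ran from 3830 (8-fold) to 6321 (2-fold), within 1.5 times of 4751, with 56.1% to 58.7% higher in replicate 2. Leaving out 1 library shows nothing about stability here, since either of 2 values always lies within 1 SD of their mean. No paired analysis was possible because there was a single group. Depth limits what a count of 0 shows to 3 counts per library.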

Other observations

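The tests on read counting, on pup differences, on antigen expression and on muscle-like thymic cells were chosen after the results they bear on were seen, and those on read counting and antigen expression replaced earlier versions. Some readings of the other tests were also settled late. For sampling of molecules, the formula, the interval of the rate and 25 to 50 TPM as the deciding range (in place of 100 to 200 TPM) were chosen with the values in view, and shares missing by read count had been seen before its bound was written. For carried-over reads, the outcome first met the bound written against it and was changed to undecided once an interval was added. The outcomes of the 3 tests on muscle transcripts were changed to undecided after counts in both libraries and the origin of the atrial genes were weighed. A further 2 tests, of why spike-ins scattered less than mouse genes, were planned and not run. Spike-ins scattered less in each of the 5 ranges of mean count with a value, from 2.33 against 5.28 at 100 to 1000 counts to 0.12 against 0.38 from 30000, with 6 to 9 spike-ins in each. The last range has no upper end, so depth within it may differ. At like TPM below 200, spike-ins were missing from 1 library more often than mouse genes. The shares were 83.3% of 6 against 37.0% at 25 to 50 TPM and 28.6% of 7 against 13.5% at 50 to 100. At 200 to 500 TPM 0 of 7 spike-ins were missing, against 0.171% of mouse genes.

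Sex-linked transcripts, which summed to 108 and 88.4 TPM, were read in opposite libraries, and the labels do not record the sex of the pups. The Y-linked genes Ddx3y (chromosome Y, 1260771 to 1286629, minus strand) and Eif2s3y had 3347 and 2366 counts in replicate 1 and 1 count each in replicate 2, ratios of 4107 (95% counting interval 737 to 162266) and 2903 (521 to 114720) after scaling to library size. Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254, minus strand), had 1 count in replicate 1 and 31835.5 in replicate 2, a ratio of 25944 (4656 to 1024758). Tsix overlaps Xist on the other strand, and its 0 and 945 counts are uncertain because reads without strand cannot be assigned to either. Uty had 0 and 1 counts and Kdm5d 0 and 0, within the floor of 3 counts per library. At 25 to 50 TPM, where the mean of Xist (39.3 TPM) lies, 37.0% of all mouse genes were also missing from 1 library. By mean count Xist lies at 10000 to 30000, where it was the sole gene among 371 at 3 or fewer counts in 1 library (0.27%). Ddx3y and Eif2s3y lie at 1000 to 3000, where 29.5% of the 3412 genes had 3 or fewer counts in 1 library.

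Many genes with over 100 counts in 1 library had 3 or fewer in the other. Read counting noise is argued against, since 3277 of the 9341 genes with a mean of 100 or more counts had 3 or fewer in 1 library, where Poisson counting of the reads expects fewer than 1. Differences between the pups as the whole cause are argued against by the spike-ins, of which 8 of the 34 with a mean of 100 or more counts had 3 or fewer in 1 library. Sampling of starting molecules at a single rate, 0.0140 per TPM from the scatter of 139 genes at 1000 TPM or more (95% bootstrap interval 0.00969 to 0.0237), predicted shares of 94.5%, 52.6% and 15.5% at 25 to 50, 50 to 100 and 100 to 200 TPM, which are 2.55, 3.90 and 3.94 times the 37.0%, 13.5% and 3.93% seen, and at the upper rate 63.8%, 21.8% and 2.99%, so it is argued against by the lower ranges and not by the highest. Sampling joined by a further source of scatter among abundant genes may account for the pattern and was not tested, and pup differences in single genes, sex-linked ones among them, stay open too.

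Muscle transcripts stood in both thymus libraries, with 12 of 16 genes of the fixed list at 10 or more counts in both and 16 in at least 1, against 1 and 2 of 22 genes of other organs. Of 16 muscle genes outside that list, 11 reached 10 counts in either library, more often than the genes of other organs (two-sided Fisher's exact p = 0.000286, counting genes as independent), as tissue next to the thymus would give and unselective expression of tissue antigens by thymic epithelium would not. In both libraries 4 of the 16 reached it (p = 0.141, Fisher's exact test). They were Sln (2007 and 187 counts), Tnni1 (1546 and 14), Tnni2 (10 and 811) and Atp2a1 (10 and 122.5). Tnnc1 fell short with 1628 and 7, while Mb and Pln had 0 in both and Myl2, Myl3 and Tcap 6 or fewer. For muscle-like thymic cells, 5 of 6 atrial genes had 10 or more counts in both libraries, but 5 of the 6 came from the fixed list whose values had been seen, so the test is void. The 3 sources cannot be told apart, since no reference profile of these cells was used and the excision protocol was not analysed here.

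Among genes at 3 or fewer counts in a library and 100 or more in the other, 383 of 2178 in replicate 1 and 432 of 1445 in replicate 2 had 1 to 3 counts. Reads carried over between the libraries could give such counts, and their share would then rise with the count in the other library, as it did from 14.8% to 25.9% and from 23.7% to 44.2%. Spearman's rho across genes, which are not independent replicates, was 0.0891 in replicate 1 (95% bootstrap interval 0.0450 to 0.133) and 0.162 in replicate 2 (0.110 to 0.208). The bound set before the test was 0.1 or lower in either direction as evidence against, which 0.0891 meets, but its interval spans the bound. Carry-over therefore cannot be told apart from other sources of single reads.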
